A study of Mus musculus with 4 samples.

How the data were processed

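Total RNA of otocysts dissected from mouse embryos of the NMRI strain at E10.5 was amplified and labelled with AlexaFluor555 or AlexaFluor647, per the labels' protocols. Each of 4 Agilent arrays received 1 mutant and 1 control RNA. The mutant RNA carried AlexaFluor647, read as red, on replicates 1 and 3 and AlexaFluor555, read as green, on replicates 2 and 4. All arrays lay on 1 slide and were scanned together, per the file headers, so no slide batch could be tested. The control labels leave open whether each carried 1 or 2 floxed copies.

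Spot intensities, with their local background intensities, were read by Agilent Feature Extraction 10.7.3.1, per the file headers and the submitters' processing notes. The same files hold log10 ratios of red over green, which the scanner software computed from background-subtracted and dye-normalized signals, per the file headers. The flags for spots well above background, non-uniform or saturated were set by the software, per the file headers. The series value table deposited by the authors holds signed fold ratios of mutant over control. Turned to log2, they lay within 0.001 of the scanner software's log2 ratios, with the direction given by the dye labels, for 90.9% to 93.3% of 39429 probes, and the median of each column was 1. How the remaining values were changed is not given in the sources used here.

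Mean spot signals were corrected for background with normexp and an offset of 50, and red over green log2 ratios were normalized within each array by loess, with control spots at weight 0, in limma 3.58.1 under R 4.3.3 (statmod 1.5.0, version 1.17.8 of data.table). Between 21 and 32 non-uniform spots per array were left out, and 0 were saturated. Spots of a probe were averaged. A probe was kept when well above background on at least 3 of 4 arrays in the mutant or the control channel, which left 23200 of 39429 probes. For each gene the kept probe with the highest mean intensity was used, which gave 18409 genes or unnamed targets, 4544 of them with clone or provisional names. Names came from a RefSeq table of assembly GRCm38.p6, used for names alone, by accession for 26520 probes, by symbol for 3785 and by synonym for 714, and 8410 kept the file's name. Coordinates are those of the files (mm9). Of 4016 genes with more than 1 kept probe, 16 had probes called in opposite directions. Over 281 probes printed 10 times, the median SD of the log2 ratio was 0.037 between the 10 spots of a probe within an array. For the spot averages of these probes, the median residual SD between arrays, after the genotype and dye terms, was 0.087.

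The log2 ratios were fitted with lmFit and eBayes (prior degrees of freedom 4.60, residual 2) with the genotype coded by dye orientation and a dye term, and p-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. SDs are of the turned ratios over the 4 arrays and include the dye effect that the fit removes. A gene not well above background in any channel of a genotype has a bound, given as "at least N-fold", from channel levels after loess and Aquantile normalization. Gene lists were tested with limma's camera (preset correlation 0.01), with the estimated correlation and fry beside it, and with Benjamini-Hochberg over the 27 lists. The list of genes on the sex chromosomes was read as a check of the sex labels and not tested. The difference between sexes was an interaction term, and calls near Tbx2, Tbx3 and Pax2 were tested with a two-sided Fisher's exact test. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.

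The genes named were Tbx2, Tbx3 and Pax2, the 12 with the largest positive and the 12 with the largest negative log2 ratio among those past the adjusted p and of 1 sign on all arrays, leaving out clone and provisional names, and for each list up to 4 members with the smallest adjusted p past 0.05 adjusted over the list alone. Not all genes that met the rule are reported here. This rule, the lists, the main tests and nearly all alternatives were fixed before the data were examined. Most tests of the flagged results were chosen after the result was seen. Twist1, AW549542 and genes in the closing paragraphs were chosen after their values were seen. Alternatives covered the background correction, the normalization, the series value table, the filter, dye and sex terms, array weights, the moderation, the probe rule, outlier spots, a separate-channel analysis and leaving out each array.

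The steps were tested on simulated data with the real backgrounds and 23184 probes. Of 100 probes changed 1.5-fold, 94 were recovered, and of 100 changed 2-fold, 96; 10 of 200 calls were unchanged probes. In a simulated sex difference of 2-fold, 145 of 200 probes were recovered and 6 unchanged probes were called. With calls placed at random 500 times, the locus test gave a median odds ratio of 0.984, and 4.8% of draws had a p under 0.05. Camera with its preset correlation gave 0 of 20 random simulated lists with a p under 0.05. The simulated noise was independent between probes, so these lists held no correlation between genes and do not test the preset value. In the real lists the estimated correlation ranged from -0.279 to 0.394. The simulation also changed 200 of 23184 probes, against 23.6% of genes called in the data. The other list tests were not simulated.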

Results

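Gene expression was measured in otocysts of mouse embryos at E10.5. The otocyst is the epithelial vesicle that gives rise to the inner ear and to the neurons of its ganglion. In the mutant embryos (Tbx2/3cDKO), floxed alleles of the T-box transcription factor genes Tbx2 and Tbx3 were recombined by a cre transgene under Pax2 control, which is active in the otic region. Controls carried floxed alleles of both genes and, by their labels, no cre. RNA of 1 mutant and 1 control sample was hybridised to each of 4 arrays with 2 dyes. Both RNAs were female on replicates 1 and 2 and male on replicates 3 and 4, and within each sex the dyes were swapped between the arrays. Between 58.4% and 63.2% of the spots were well above background, and the number of arrays, 4, limits the precision. No label says whether the pairs came from separate animals or pools, so the p-values measure only the spread between these samples, which may be technical. Across genes, the log2 ratios of mutant over control correlated between arrays with Pearson r from 0.662 (replicates 1 and 4) to 0.857 (replicates 1 and 2), genes not being independent replicates.

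Tbx3, 1 of the 2 targeted genes, fell on every array. Its log2 ratio was -3.43 ± 0.16 (SD, n = 4 arrays), which is 10.8-fold lower in the mutant, with a limma SE of 0.07 and an adjusted p of 4.24e-06. The probe lies on chromosome 5 at 120134511 to 120134570 (mm9), and the 4 arrays ranged from -3.61 to -3.25. Tbx2 had a log2 ratio of 0.06 ± 0.23 (SD, n = 4 arrays; limma adjusted p = 0.650) at a probe on chromosome 11, 85655391 to 85655450 (mm9). Which part of Tbx2 is deleted is not given in the sources used here, so this probe does not check the deletion of Tbx2. Pax2, whose regulatory sequence drives the cre, had a log2 ratio of -0.09 ± 0.17 (SD, n = 4 arrays, limma adjusted p = 0.426). Its probe was dim, with mean log2 levels of 7.07 in the mutant and 7.17 in the control. In the mutant it was well above background on 3 of 4 arrays, so it does not show that Pax2 was unchanged. Xist, which is transcribed from the inactive X chromosome, had a log2 level of 9.36 to 9.68 in all RNAs labelled female. The Y-linked gene Ddx3y had a level of 10.6 to 11.0 in all RNAs labelled male and was not well above background in those labelled female. Another Y-linked gene, Eif2s3y, was low but well above background in both RNAs of replicate 2, labelled female, at 6.82 in the mutant and 7.02 in the control, against 10.4 to 11.0 in the male RNAs. In the male mutant RNA of replicate 4, Xist was also well above background, at 7.56 and 7.74 with its 2 probes, against 6.62 and 6.47 in the control RNA of that array, where it was not.

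The first comparison asks which transcripts differ between Tbx2/3cDKO and control otocysts, as the series title states. Besides Tbx3, the largest falls among named genes were in Aldh1a2, which makes retinoic acid, with a log2 ratio of -3.15 ± 0.52 (SD, n = 4 arrays), and in Gdf6, a Bmp family ligand, with -3.10 ± 0.24. Gdf6 was well above background in the mutant on 1 of 4 arrays, so the size of its fall is uncertain. Otx2 and Hmx2, homeobox genes of the ventral and the dorsal otocyst, also among the 12 largest falls, had log2 ratios of -2.18 ± 0.29 and -1.94 ± 0.13. The largest measured rise was in Prm1, a sperm chromatin protein gene, which was well above background in the mutant on 4 of 4 arrays and in the control on 0 of 4, at least 32.6-fold higher in the mutant. Among named genes well above background in both genotypes on all arrays, the largest rises were in Esm1, made by endothelial cells, with a log2 ratio of 2.96 ± 0.27, and in Napsa, an aspartic protease gene, with 2.85 ± 0.17.

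Of 18409 genes or unnamed targets tested with limma, 2482 (13.5%) were higher and 1867 (10.1%) lower in the mutant at a Benjamini-Hochberg adjusted p under 0.05. At least 1.5-fold was reached by 617 of the higher and 354 of the lower ones. Without replicate 3 there were 1560 higher and 1026 lower, and without replicate 1 the lower count was 1148. The fit to 3 arrays leaves 1 fewer degree of freedom for the residual.

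**Figure D1:**
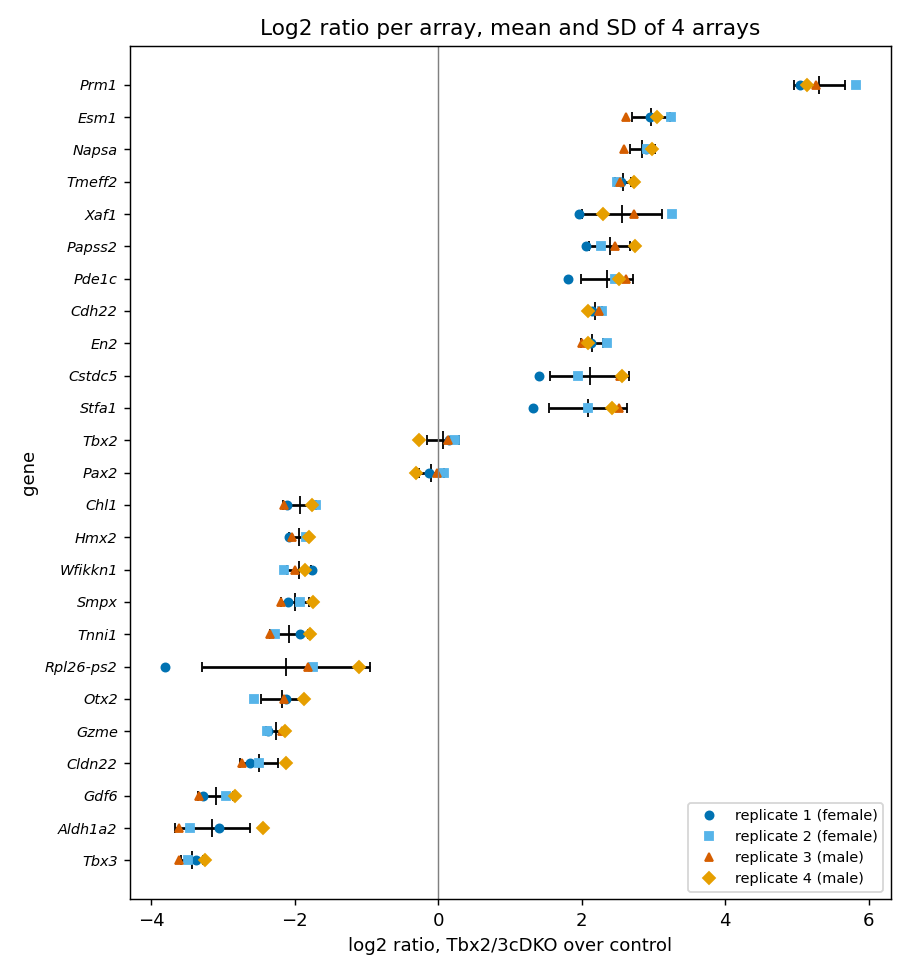
Log2 ratio of mutant over control (x axis) for Tbx2, Pax2 and the reported ones of the 12 genes with the largest positive and the 12 with the largest negative ratio (y axis). Symbols are the 4 arrays, the vertical tick is the fitted log2 ratio and the horizontal bar 1 SD of the arrays. Tbx3 lies near -3.43, while the values of Tbx2 and Pax2 spread around 0. Prm1, En2, Stfa1 and Xaf1 were not well above background in any control channel and Gzme in any mutant channel, so their places are not exact ratios.

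The other named genes with large rises belonged to several kinds of protein. Tmeff2, a transmembrane protein with follistatin domains, had a log2 ratio of 2.57 ± 0.11 (SD, n = 4 arrays) with the probe used and 1.04 with its other kept probe, and Cdh22, a cadherin, had 2.19 ± 0.09. Papss2, which makes the sulfate donor of matrix sugars, had 2.39 ± 0.29, and Pde1c, a cyclic nucleotide phosphodiesterase, 2.35 ± 0.37. En2, a homeobox gene of the midbrain-hindbrain boundary, was not well above background in any control channel and was at least 4.2-fold higher. Stfa1, a stefin of myeloid cells, was in the same way at least 3.65-fold higher, and Cstdc5, of the same family, had a log2 ratio of 2.11 ± 0.55, its control being well above background on 2 of 4 arrays. Related stefin genes may share probe sequence, so the gene that gave these signals is uncertain. Xaf1 was at least 4.82-fold higher with the probe used, while its other kept probe had a log2 ratio of -0.58, so its direction is not settled.

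Among the genes with large falls, Cldn22, a tight junction claudin, had a log2 ratio of -2.49 ± 0.26 (SD, n = 4 arrays), Chl1, a neural adhesion molecule, -1.93 ± 0.23 (-1.29 with its other kept probe), and Wfikkn1, a secreted binding protein of growth factors, -1.94 ± 0.17. Tnni1, a troponin of slow muscle, and Smpx, a small protein of muscle and inner ear, had log2 ratios of -2.08 ± 0.26 and -1.99 ± 0.20. In the mutant Smpx was well above background on 1 of 4 arrays and Chl1 on 2 of 4, so the sizes of these falls are uncertain. Gzme, a granzyme gene, was not well above background in any mutant channel and was at least 3.77-fold lower with the probe used, while its other kept probe had a log2 ratio of -1.68; granzyme genes may share probe sequence. The probe named for the pseudogene Rpl26-ps2 had -2.12 ± 1.17, from -3.81 on replicate 1 to -1.11 on replicate 4, and may read other copies. All these genes passed a limma adjusted p of 0.05, the largest being 0.00261 for Rpl26-ps2.

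A second count needs no model of the spread. 360 genes were at least 1.5-fold higher on each of the 4 arrays, and 211 at least 1.5-fold lower, Tbx3, Gdf6, Otx2 and Hmx2 among them. At 2-fold on each array the counts were 105 and 70. With the ratios of the scanner software in place of the normexp and loess values, 574 genes were higher and 386 lower at 1.5-fold, and with the deposited series values there were 573 and 392.

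The second question was which groups of genes moved, for 27 lists fixed before the data were examined. Genes of the dorsal otocyst and endolymphatic duct fell: of 17 tested, 11 were lower and 3 higher over all genes tested (12 and 3 adjusted over the list alone), with a median log2 ratio of -0.49 (camera adjusted p = 2.00e-05, and 0.281 with an estimated correlation). Gbx2 had a log2 ratio of -1.50 ± 0.10 (SD, n = 4 arrays), Dlx5 -1.19 ± 0.22 and Oc90, a matrix protein of the otoconia, -1.83 ± 0.24, while Bmp2, a member of the list, had 0.72 ± 0.10. Genes of the ventral and non-neural lateral otocyst had a median of -0.43, with 10 of 18 lower and 5 higher over all genes tested and the same counts adjusted over the list alone (camera adjusted p = 0.0127, and 0.329 with an estimated correlation). Otx1 had -1.71 ± 0.06, Gata2 -1.50 ± 0.19, and Ntn1, an axon guidance and basement membrane factor, went the other way with 1.81 ± 0.14. General otic epithelium genes had a median of -0.24, with 13 of 22 lower and 3 higher over all genes tested and adjusted over the list alone (camera adjusted p = 0.00184, and 0.367 with an estimated correlation). Pax8 had -0.65 ± 0.04, Krt8, an epithelial keratin, -0.81 ± 0.11, and Sall4 -0.85 ± 0.19 (-0.47 and -0.49 with its other kept probes). On the same arrays the erythroid list had a median of 1.13.

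Genes of otic neuroblasts and early neurons rose: 24 of 32 tested were higher and 1 lower over all genes tested (26 and 1 adjusted over the list alone), with a median log2 ratio of 0.70 (camera adjusted p = 3.09e-14, and 0.281 with an estimated correlation). Nefm, a neurofilament, had a log2 ratio of 1.65 ± 0.07 (SD, n = 4 arrays), Pou4f1, a factor of sensory neurons, 1.53 ± 0.08, Dll3, a Notch ligand relative, 1.78 ± 0.19, and Ina, another neurofilament, 1.27 ± 0.12. The hindbrain list, measured on the same arrays, had a median of -0.10 with 2 of 10 tested genes higher and 2 lower (camera adjusted p = 0.592), Pax3 having 1.05 ± 0.21 (0.60 with its other kept probe) and Hoxb2 -0.41 ± 0.24. On these arrays the medians of the erythroid, endothelial, mesenchyme and dissection stress lists were 1.13, 0.63, 0.32 and 0.28.

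Among signalling lists, Fgf ligands and feedback targets rose, with 11 of 20 higher and 4 lower over all genes tested (13 and 4 adjusted over the list alone), a median of 0.32 and a camera adjusted p of 0.00229 (0.281 with an estimated correlation). Fgf8 had a log2 ratio of 1.98 ± 0.12 (SD, n = 4 arrays) with the probe used and 1.37 and 0.46 with its other kept probes, Dusp6, a feedback phosphatase, 0.86 ± 0.14, and Fgf9 0.66 ± 0.09, while Fgf20 had -0.67 ± 0.12. Notch pathway genes had a median of 0.22, with 10 of 19 higher and 2 lower over all genes tested (11 and 3 adjusted over the list alone; camera adjusted p = 0.00801, and 0.515 with an estimated correlation), Heyl having 0.83 ± 0.13 and Mfng 0.68 ± 0.20. Of the 10 higher genes, 4 (Dll1, Dll3, Mfng and Hes6) are members of the neuronal list too. Bmp pathway genes fell, with 11 of 20 lower and 2 higher over all genes tested (12 and 2 adjusted over the list alone), a median of -0.22 and a camera adjusted p of 0.00120 (0.490 with an estimated correlation). Smad9, a signal transducer, had -1.04 ± 0.16. Among the 11 are Gata2, also in the ventral list, Msx1, also in the dorsal list, and Bmp4, also in the prosensory list. Bmp2, of the dorsal list too, had 0.72 ± 0.10, and Bmp6 had 0.61 ± 0.07. The erythroid, endothelial and dissection stress lists, with medians of 1.13, 0.63 and 0.28, were measured on the same arrays.

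Of the 8 lists of other cells, 4 passed with camera's preset correlation, all higher, and 0 with an estimated correlation. All 15 erythroid genes tested were higher (15 adjusted over the list alone), with a median log2 ratio of 1.13 (camera adjusted p = 1.21e-15, and 0.281 with an estimated correlation); the embryonic globin genes Hbb-bh1 and Hbb-y had log2 ratios of 1.45 ± 0.25 and 1.29 ± 0.47 (SD, n = 4 arrays). All 14 endothelial genes were higher (14 adjusted over the list alone), with a median of 0.63 (camera adjusted p = 5.97e-10, and 0.281 with an estimated correlation), Sox17 having 0.79 ± 0.07 and Pecam1, a junction protein of vessels, 0.66 ± 0.04. Macrophage genes had a median of 0.37, with 9 of 13 higher over all genes tested and adjusted over the list alone (camera adjusted p = 1.18e-05, and 0.374 with an estimated correlation), Lyz2 having 0.65 ± 0.13. Periotic mesenchyme genes had a median of 0.32, with 14 of 20 higher over all genes tested (14 higher and 2 lower adjusted over the list alone; camera adjusted p = 5.66e-06, and 0.281 with an estimated correlation). Osr1 had 1.24 ± 0.17 and Foxc2 1.18 ± 0.17, whereas Twist1, a broad mesenchyme factor, had 0.09 (limma adjusted p = 0.297).

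The extracellular matrix list had a median of 0.24, with 13 of 24 higher and 1 lower over all genes tested (13 and 3 adjusted over the list alone), and a camera adjusted p of 0.000749, against 0.573 with an estimated correlation and 0.0727 by fry. On replicate 4 the list median was 0.03, against 0.29 to 0.42 on the other arrays. The basement membrane gene Nid1 had 0.75 ± 0.04 (SD, n = 4 arrays) with the probe used and 0.58 and 0.23 (limma adjusted p = 0.0704) with its other kept probes, and Fbln2 had 0.76 ± 0.02, while the cartilage collagen gene Col9a3 had -0.81 ± 0.12. The dissection stress list had a median of 0.28, with 7 of 12 higher over all genes tested (11 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.000194, and 0.281 with an estimated correlation), Egr1 having 1.27 ± 0.20 and Fos 0.67 ± 0.19. The erythroid median of 1.13 and the endothelial median of 0.63 stand beside these rises.

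Of the 27 lists, 13 passed a camera adjusted p of 0.05, 9 higher and 4 lower. None of the 13 passed with an estimated correlation, where the adjusted p ranged from 0.281 to 0.573. For the dissection stress, Fgf, ventral and periotic mesenchyme lists the estimated correlation was -0.087, -0.020, -0.057 and 0.0094, below the preset 0.01. A higher correlation thus did not raise their p-values. That test rests on the 2 residual degrees of freedom, so the loss of all 13 lists does not separate correlation between genes from low power. By fry, which asks whether a list's genes move one way on balance without comparing them with other genes, 12 of the 13 passed, the matrix list not (adjusted p = 0.0727).

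**Figure D2:**
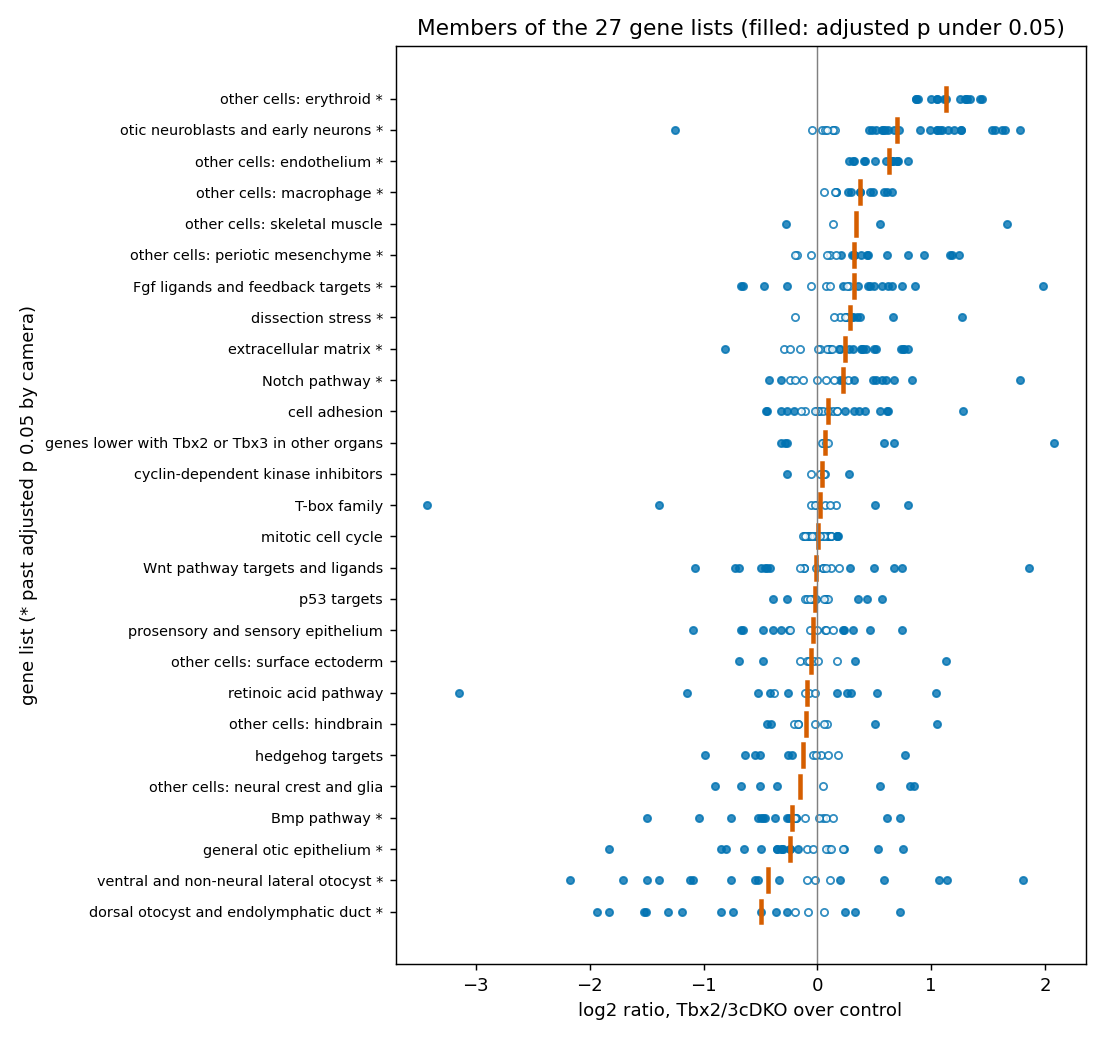
Log2 ratio of mutant over control (x axis) of each tested member (points, filled at a limma adjusted p under 0.05) of the 27 lists (y axis), with the list median as an upright bar. An asterisk marks the 13 lists past a camera adjusted p of 0.05, from erythroid (median 1.13) to dorsal otocyst genes (median -0.49).

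The mitotic and kinase inhibitor lists had medians near 0. The 27 mitotic cell cycle genes tested had a median log2 ratio of 0.01 (camera adjusted p = 0.716). Over all genes tested 2 were higher and 0 lower, and adjusted over the list alone 0 were higher and 0 lower. Of 6 cyclin-dependent kinase inhibitor genes tested, Cdkn1a, which T-box factors repress in other cells, had -0.27 ± 0.11 (SD, n = 4 arrays; limma adjusted p = 0.0136) and Cdkn2c 0.28 ± 0.05 (limma adjusted p = 0.00797), the list having a median of 0.04 (camera adjusted p = 0.903). With the mean of its probes Cdkn1a had an adjusted p of 0.117. Without replicate 3, Cdkn1a had an adjusted p of 0.106 and Cdkn2c one of 0.0596, and without replicate 1 Cdkn2c had one of 0.0506. Of 17 p53 target genes, 3 were higher and 2 lower (camera adjusted p = 0.907), with Btg2 at 0.57 ± 0.07 and Phlda3 at -0.39 ± 0.03. The list of genes that are lower with Tbx2 or Tbx3 in other organs had a median of 0.07, with 3 of 11 higher and 3 lower (camera adjusted p = 0.438), Gja5, a gap junction gene, having 2.08 ± 0.18 and Cdh1 -0.32 ± 0.18.

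In the retinoic acid list, 5 of 14 genes were higher and 5 lower (median -0.09, camera adjusted p = 0.264). Beside Aldh1a2, Cyp26c1, which breaks down retinoic acid, had a log2 ratio of -1.15 ± 0.19 (SD, n = 4 arrays) and its relative Cyp26b1 1.04 ± 0.37. In the Wnt list 5 of 21 were higher and 7 lower (median -0.01, camera adjusted p = 0.438), with Sfrp2 at 1.86 ± 0.18 and Dkk1 at -1.07 ± 0.16. Among hedgehog targets 1 of 12 was higher and 6 lower (median -0.13, camera adjusted p = 0.0803), with Cdon at -0.98 ± 0.14 (-0.61 with its other kept probe) and Gli1 at -0.64 ± 0.24. This list passed with median centring (adjusted p = 0.0268), without replicate 1 (adjusted p = 0.0372) and without replicate 2 (adjusted p = 0.00916), but had 0.660 with an estimated correlation. Among prosensory genes 5 of 18 were higher and 7 lower (median -0.03, camera adjusted p = 0.438), with Gata3 at -1.10 ± 0.22 and Lgr5 at 0.74 ± 0.11. Of 10 T-box genes tested, Tbx1 had -1.39 ± 0.16 and Tbx18 0.79 ± 0.11 (list camera adjusted p = 0.903); the list holds the deleted gene Tbx3, so its tests do not speak for the other members. The cell adhesion list had 8 of 25 higher and 5 lower (median 0.09, camera adjusted p = 0.189), with Pcdh17 at 1.28 ± 0.25. Neural crest and glia genes had 3 of 8 higher and 4 lower (median -0.15, camera adjusted p = 0.716), with Fabp7 at 0.85 ± 0.20. Surface ectoderm genes had 2 of 10 higher and 2 lower (median -0.05, camera adjusted p = 0.677), and skeletal muscle genes 2 of 4 higher and 1 lower (median 0.34, camera adjusted p = 0.126), Actc1 having 1.66 ± 0.11. With median centring the muscle list, of 4 tested genes, passed (adjusted p = 0.0268), and with an estimated correlation it had 0.490. By fry the muscle (adjusted p = 0.000471), retinoic acid (0.00578), cell adhesion (0.0306) and other-organ (0.0422) lists passed, and so did the T-box list with Tbx3 in it (0.00578). Median, mean and test differed in sign for the T-box list (median 0.03, mean -0.33 with Tbx3 in it, test lower), the p53 list (-0.02, 0.04, higher), the hindbrain list (-0.10, 0.03, lower) and the surface ectoderm list (-0.05, 0.01, lower).

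A further comparison asked whether the effect of the genotype differed between female and male pairs, which the labels provide with 2 arrays each. Myl1, a myosin light chain of muscle, rose less in female than in male pairs. Its mean log2 ratio was 1.31 in female pairs (1.14 and 1.47) and 2.81 in male pairs (2.77 and 2.86), a difference of -1.50, female minus male (limma adjusted p = 0.0199). D8Ertd158e, a transcript of unknown function, had 0.39 in female and -0.76 in male pairs, a difference of 1.15 (limma adjusted p = 0.0286). These 2 genes passed the adjusted p among 18409 tested, and 2857 (15.5%) had an unadjusted limma interaction p under 0.05. No label says whether the 2 pairs of a sex came from separate animals. A difference between these particular pairs therefore cannot be told apart from one between the sexes. With 1 residual degree of freedom the test rests on the moderation across genes. Without the dye term D8Ertd158e had an adjusted p of 0.313, and with the ratios of the scanner software Myl1 had one of 0.0643 and D8Ertd158e one of 0.0778, while 2 other genes passed.

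The last comparison asked whether calls gathered near Tbx2, Tbx3 and Pax2, since floxed alleles can carry linked sequence of another strain. Where the cre transgene lies is not given in the sources used here. The window at Pax2 therefore does not test sequence linked to the transgene. Called were 25 of 115 genes near Tbx2, 28 of 153 near Tbx3 and 29 of 122 near Pax2. Of 390 tested genes within 5 Mb of Tbx2, Tbx3 or Pax2, these left out, 82 (21.0%) were called, against 23.6% of the genes elsewhere, with an odds ratio of 0.862 (95% confidence interval 0.666 to 1.11; two-sided Fisher's exact p = 0.252). Near Tbx3, the transcript AW549542 at 120020143 to 120020202 on chromosome 5 (mm9) had a log2 ratio of -3.07, being well above background in the control on 4 of 4 arrays and in the mutant on 1 of 4. Within 5 Mb of Pax2, Fgf8 had 1.98 ± 0.12 (SD, n = 4 arrays; 1.37 and 0.46 with its other kept probes) and the neurofilament gene Ina 1.27 ± 0.12 (1.04 with its other kept probe).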

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

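The tests of more blood and vessel cells, of boundary tissue and of spermatid transcripts were written before their results were seen; the other tests here were chosen after the result was seen.

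Markers of blood and vessels were higher in the mutant while otic epithelium markers were lower. A smaller share of epithelium with the other cells in unchanged proportions would raise all other cell types alike. The erythroid median lay 1.28 (log2) above that of the neural crest and glia list, more than their combined SD of 0.716. That list was taken because its median was the lowest. Of its 8 tested genes 3 were higher and 4 lower, and it shares Sox10 with the otic epithelium list. The medians of the other-cell lists ranged from -0.15 to 1.13, so the rises were unequal. The gap between the ends of that range is no test of unequal proportions and does not decide the question. Of 17 dorsal members, 6 (Dlx5, Dlx6, Hmx2, Hmx3, Gbx2 and Oc90) lay below Krt8, the lowest of 8 pan-epithelial markers, by more than 2 SE. As sets they did not separate, with a dorsal median of -0.49 (SD of members 0.80) and a pan-epithelial median of -0.32. Pan-epithelial markers are not restricted to the otocyst, and the surface ectoderm list had a median of -0.05. A smaller otic share could therefore lower otic genes more than these markers, so dilution as the whole source of the lower dorsal genes stays open. More blood and vessel cells in the mutant RNA remain open: of 28 tested markers from outside the fixed lists, 20 were higher and 1, Tspo2, was lower, under the 4 in 5 set beforehand, with 12 of 14 endothelial and 9 of 15 erythroid markers higher and Tal1 counted in both. A change of these cells that comes with the genotype, where the lowest array median of the erythroid and endothelial lists was 0.53, and a difference in dissection cannot be told apart, since each mutant RNA came from mutant tissue alone.

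Neuronal genes were higher in the mutant. For hindbrain tissue in the mutant RNA as their source, the hindbrain list median lay 0.79 below the neuronal median. This was more than the SD of its members, 0.452. Of its 24 genes 10 were tested, of which 2, Pax3 and Dbx1, were higher and 2 lower. En2, which is not in the list, was higher too. Genes of this list need not rise as much as neuronal genes in added hindbrain tissue, so the gap does not decide the question. For tissue of the midbrain-hindbrain boundary, Wnt1, Lmx1b and Fgf17 were the tested ones of 5 boundary genes, and 0 of them were called higher. En2, a boundary gene outside these 5, was at least 4.2-fold higher, so boundary tissue as a source is not settled. More ganglion neurons or neuroblasts with the genotype, with a lowest array median of 0.64 for the neuronal list, stay open and cannot be told apart from tissue taken along at dissection by these data.

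Prm1 gave a signal in the mutant channels alone. Spermatid transcripts in the mutant RNA are argued against by 12 other spermatid genes, among them Prm2, Tnp1 and Tnp2, of which 0 were well above background on all mutant channels and no control channel; of the 3 tested, Ldhc was higher (0.53) and Tssk6 lower (-0.26), both well above background in all channels. A candidate explanation is Prm1 sequence carried by the cre transgene, which the mutants have and the controls by their labels lack; the lower bound of 32.6-fold goes with it, but the transgene sequence is not used here and the design confounds it with the genotype, so it cannot be told apart from expression of Prm1 itself.

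Of 115 named genes, 6 had 1 array far from the other 3 by Dixon's test at its 95% critical value for 4 arrays; chance gives about 1 in 20. Replicate 4 stood apart for Bmp2 (0.57 against 0.76 to 0.79), Nid2 (0.48 against 0.80 to 0.85) and Plk2 (0.49 against 0.29 to 0.32). Replicate 2 stood apart for Meox1 (0.83 against 1.24 to 1.31), replicate 3 for Cdon (-0.77 against -1.07 to -1.03) and replicate 1 for Fgf20 (-0.85 against -0.63 to -0.59). Of 27 list medians, 2 had an array apart, both replicate 4: skeletal muscle (0.49 against 0.29 to 0.29) and Wnt pathway (-0.23 against 0.00 to 0.03).

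The effect of the genotype differed between the female and male pairs for Myl1, by -1.50 (log2, female minus male, limma interaction adjusted p = 0.0199). For D8Ertd158e the difference was 1.15 (adjusted p = 0.0286). Both genes had 2 arrays per sex, which may not come from separate animals, so the difference may be one between these pairs. With the scanner software's ratios neither passed (adjusted p = 0.0643 and 0.0778), and without the dye term D8Ertd158e did not (0.313). The male mutant RNA of replicate 4 also gave an Xist signal.

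Other sign patterns of the 4 arrays were fitted in the same way. The real pattern gave 4349 called genes and the highest of the other patterns 0, with 1 of 7 patterns as large; for 1.5-fold on every array the real pattern gave 571 genes and the highest other 1, with 1 of 8 as large; for the gene lists the real pattern gave 13 and the highest other 10, with 1 of 7 as large. So few patterns cannot give a share under 0.05. They are also no clean null. The patterns that gave 7 to 10 lists differ from the real one, or from its reverse, on 1 array, so they carry part of the genotype effect. The remaining fitted patterns gave 2 and 0 lists. Under any other pattern the genotype effect also enters the residual, which lowers the number of called genes.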

How the results depend on the processing

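All alternatives were fixed before the data were examined except leaving out arrays in the locus test, which was added afterwards. The counts of genes higher and lower stayed within 1.5 times of 2482 and 1867 under every alternative but the fold threshold and left-out arrays. Requiring 1.5-fold gave 617 and 354, by its construction. Leaving out 1 array gave 1560 to 2492 higher and 1026 to 1786 lower, with 1 residual degree of freedom and the lone array of a dye orientation assumed to vary like the others. For 1.5-fold on every array (360 higher, 211 lower), the scanner software's ratios gave 574 and 386 and the deposited series values gave 573 and 392, and the cause was not tested; the 2-fold rule gave 105 and 70 by its construction, and leaving out 1 array gave 392 to 427 and 228 to 240. The 2 genes that differed by sex became 1 without the dye term, and with the scanner software's ratios 2 others passed in their place, the causes not tested. Leaving out an array there leaves no residual degree of freedom, so it was not run. The 13 gene lists became 0 with an estimated correlation, a test that rests on 2 residual degrees of freedom, and 13 to 14 with an array left out. The odds ratio near Tbx2, Tbx3 and Pax2 ranged from 0.760 to 0.939 with 1 array left out and did not pass under any window. Uncalled values changed sign as follows, the cause not tested: with 1 array left out, Pax2 ranged from -0.19 to 0.0047 (turned without replicate 4) and Tbx2 from -0.062 to 0.19 (turned without replicate 2). For lists, the test's direction turned for kinase inhibitors (median 0.041 with median centring, -0.0097 to 0.040 with 1 array left out, turned without replicate 3), mitotic genes (-0.0015 with median centring, -0.0039 to 0.046 with 1 array left out, turned without 3 or 4), p53 targets (-0.038 to 0.050 with 1 array left out, turned without 3 or 4), T-box genes (0.016 with the scanner software's ratios, -0.014 to 0.055 with 1 array left out, turned without 1) and hindbrain genes (-0.10, by fry). Cdkn1a, Cdkn2c, Nkx6-1, Tfap2c and Tnnt2 lost their call with an array left out, and Cdkn1a with the mean of probes; the other named genes kept theirs under every alternative that tested them. A slide block was not run because 1 slide held all arrays. Between 58.4% and 63.2% of the spots per channel were well above background, which limits the genes tested.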

Other observations

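These genes and their grouping were chosen after their values were seen, so the counts are descriptions. Of 6 tested homeobox genes of the Dlx family, 5 were lower in the mutant. Dlx1 and Dlx2, neighbours on 1 chromosome, had log2 ratios of -1.84 and -1.83, beside Dlx5 and Dlx6 of the dorsal list at -1.19 and -1.31 and Dlx4 at -0.22, while Dlx3 had 0.06 (limma adjusted p = 0.492). Hmx1, a relative of Hmx2 and Hmx3, had -0.97. The POU factor genes Pou3f3 and Pou3f1 had 1.66 and 0.99, and Pantr1, a noncoding transcript beside Pou3f3, had 1.93. Cxcl12, a chemokine that guides migrating cells, had 1.53.

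Muscle genes went in both directions: Myl1 and Actc1 had log2 ratios of 2.06 and 1.66 and Tnnc2 1.00, whereas Tnni1 had -2.08 and Smpx -1.99. Of myeloid genes, the calgranulin genes S100a8 and S100a9 were at least 2.29-fold and 3.87-fold higher, neither being well above background in any control channel. Mpo, a neutrophil granule enzyme gene that lies within 5 Mb of Tbx2, had 1.13, while Elane, of the same granules, had 0.00 (limma adjusted p = 0.968). Besides Gzme, the granzyme genes Gzmn and Gzmg, not well above background in any mutant channel, were at least 2.56-fold and 1.33-fold lower, with the caution on shared probe sequence given for Gzme.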
